A study of Mus musculus with 10 samples.

How the data were processed

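RNA was measured in 10 libraries from mouse hemi-mandibles, 5 of ameloblasts and 5 of stratum intermedium, each set with 2 WT and 3 claudin-10 KO libraries. Per the labels' protocols, frozen slides were laser-captured with an ArcturusXT instrument for at most 2 h, RNA was extracted with the RNeasy Micro kit, and stranded polyA libraries were made with a TruSeq kit from 1 µg of total RNA with an RNA integrity number above 8. The age, sex and strain of the mice, the part of the enamel organ that was captured and the deleted part of Cldn10 are not given in the sources used here.

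The signal values were deposited as a table of normalized counts per gene for each cell type, which the submitters named as a DESeq2 normalized matrix. Per the submitters' processing notes, the genome build was GRCm38 and the tools were FastQC, STAR 2.5.2b, Picard 2.8.1, featureCounts and DESeq, with no settings or order stated. The name of each table gives Ensembl release 101 and says that outliers were left out, without saying which. All genes listed had a value of at least 10 in at least 3 libraries of their table, as read from the values, so genes under that floor were not seen. With 3 KO and 2 WT libraries, a gene could be listed through the KO libraries alone but not through the WT libraries alone. Between 54.5% and 72% of the low values of a library lay near whole steps, so whole reads could not be recovered, and no test on read counts was made. Without read counts the sequencing depth behind each value is unknown, and no counting intervals were given. The values summed to between 21006977 and 26856177 per library.

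Columns were matched to the samples by library name, and 0 columns were left unused. The prefix of the library name (WT10, WT5, KO1, KO3 or KO9) was taken to mark the mouse in both tables. The group number at the end of the library names, from 1 to 3, is not explained in the sources used here. Sex was read from Xist and 4 Y-linked genes. Symbols were those of the tables, with 22 of 29 blank symbols in ameloblasts and 28 of 39 in stratum intermedium filled from the GENCODE annotation of GRCm38, which also gave positions. Of the gene identifiers, 16278 of 16292 and 16619 of 16638 were found there. Reads of genes that overlap in the annotation cannot be separated in these tables.

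Differences were tested within each table with limma 3.58.1 in R 4.3.3 (trend, two-sided) on log2(normalized count + 1), for genes with a mean of at least 10, which left 16212 genes in ameloblasts and 16543 in stratum intermedium. Log2 differences are KO minus WT, with standard errors from limma, and means are given with the SD over 2 WT and 3 KO libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The difference between cell types was tested with limma on the ameloblast minus stratum intermedium log2 value of each prefix, over 15567 genes past the filter in both tables. A constant factor between the separately normalized tables cancels in that test. Gene groups were tested with camera at a preset correlation of 0.01 over 41 lists, 25 of pathways and 16 of cell type markers, with an estimated correlation and with fry beside it. Marker shares were compared by exact permutation over 10 arrangements, for which 0.1 is the smallest p.

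Cldn10 was named first in each comparison. As fewer than 10 genes passed the threshold, the 10 genes with the smallest p-values whose WT and KO libraries did not overlap were named in each cell type, as not past the threshold, together with the members of each list with the smallest p-values and the 5 genes with the smallest p-values of the difference test. Some widely known members of lists, such as Amelx, Ambn, Mmp20 and Sp6, were added for their role, and genes shared by both cell types were named after their values were seen. Tests, lists, the naming rule and most alternatives were fixed before the data were examined.

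The alternatives were pseudocounts of 0.5 and 8, no filter or a mean of at least 50, quantile normalization, rescaling by median ratios without mitochondrial, haemoglobin and the 20 most abundant genes, robust variance, library weights, an adjusted p threshold of 0.1, replicate number or library group as a block, and leaving out each library or prefix. A fit with sex as a covariate was added after the data were seen. Limma, and camera at the preset correlation, were tested on simulated data drawn from the libraries' own means and spreads. For limma, 200 genes were changed by known amounts. For camera, a list of 20 genes was shifted by 1 on the log2 scale. That list passed and 0 unshifted lists did, with no correlation between genes simulated. Camera with an estimated correlation, fry and the exact permutation were not simulated. Each gene's estimated spread was taken as its true spread and genes were drawn independently, so recovery in the data may differ. Library weights used statmod 1.5.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.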

Results

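The dataset held 10 RNA-seq libraries of the mouse enamel organ, the epithelium that forms tooth enamel. Ameloblasts, the cells that secrete the enamel matrix and later mature it, and the stratum intermedium, the cell layer that backs them, were captured separately by laser microdissection from frozen sections of hemi-mandibles. The mice were wild type (WT) or knockout (KO) for claudin-10, a claudin that forms paracellular ion channels in tight junctions. Each cell type had 2 WT and 3 KO libraries. The library names carried 5 prefixes (WT10, WT5, KO1, KO3 and KO9) that recurred in both cell types and were taken as 5 mice, which the labels do not state. If the libraries did not come from separate mice, the p-values measure only the spread between these libraries, which may be technical. The deposited values were normalized counts per gene, listed for 16292 genes in ameloblasts and 16638 genes in the stratum intermedium. They summed to between 22135034 and 26856177 per ameloblast library and to between 21006977 and 24053340 per stratum intermedium library. Both tables had been normalized separately, so levels were not tested between the cell types.

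Cldn10 was lower in every KO library than in every WT library of the same cell type. Its locus (ENSMUSG00000022132) lies on chromosome 14, from 118787908 to 118875489 in GRCm38. In the stratum intermedium it averaged 4811 ± 3459 normalized counts in WT (SD, n = 2) and 618.2 ± 335 in KO (SD, n = 3), which left 13.7% of the WT level on the log2(value + 1) scale (log2 difference -2.87, SE 0.56). In ameloblasts it averaged 675.9 ± 107 in WT and 278.9 ± 130 in KO, which left 38.4% (log2 difference -1.38, SE 0.46). With limma, the p-values adjusted over these 2 tests were 0.0024 in the stratum intermedium and 0.0208 in ameloblasts, and over all genes tested they were 1 and 0.989. Two-sided exact permutation p-values were 0.1 and 0.2, where 0.1 is the smallest that 2 against 3 libraries allow. The ameloblast difference lost its call with library weights (log2 -0.97, unadjusted p = 0.113 in limma) and without WT replicate 2 (log2 -1.22, unadjusted p = 0.0897 in limma). The stratum intermedium difference was -2.06 without WT replicate 1 and -3.68 without WT replicate 2. Which part of the gene was deleted is not given in the sources used here, and the values are sums over the whole gene.

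**Figure D1:**
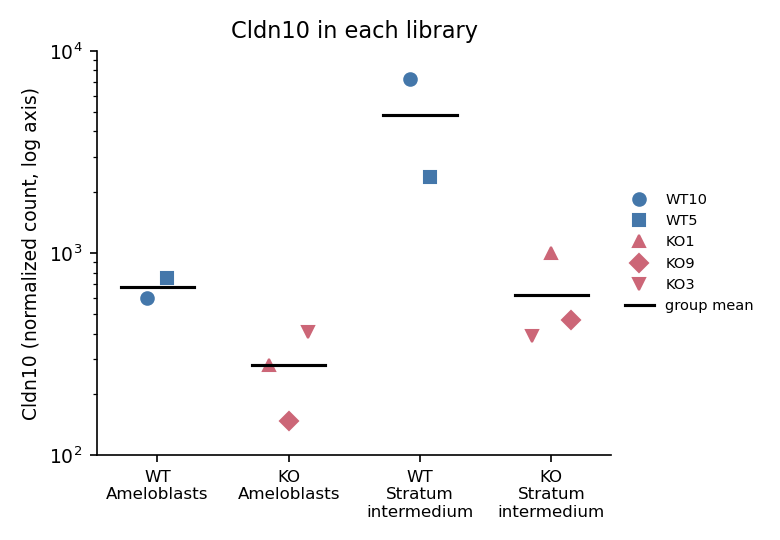
Cldn10 in each library, as normalized counts on a log axis, for WT and KO ameloblasts and stratum intermedium; each point is 1 library, with symbols for the library prefixes, and lines mark group means. The KO stratum intermedium libraries lay between 387.1 and 1003, below the WT libraries at 2365 and 7257.

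Sex-linked genes set libraries of the same genotype apart. Xist, which is transcribed from the inactive X chromosome of females, stood between 5791 and 9555 in the libraries of prefixes KO1 and KO3 and at or below 33.2 in the others. The Y-linked gene Ddx3y was listed at 0 in those same libraries of KO1 and KO3 and at 1980 or more in those of WT10, WT5 and KO9. Both WT prefixes and 1 of the 3 KO prefixes therefore carried Y-linked transcripts. WT replicate 1 had the most genes listed at 0 in each table, 706 in ameloblasts and 854 in the stratum intermedium, against 33 and 36 in WT replicate 2, and these 2 libraries were correlated across genes at r = 0.859 and 0.862. Haemoglobin and other red blood cell markers made up 0.244% and 1.28% of the WT ameloblast libraries and 0.0814% to 0.144% of the KO libraries (exact permutation p = 0.1). Skeletal muscle markers made up 0.0193% of ameloblast WT replicate 1 and 0.0699% to 0.368% of the other 4 ameloblast libraries. Odontoblast and pulp markers made up 2.59% to 4.41% of the ameloblast libraries and fibroblast markers 2.46% to 4.78%, lists that share Col1a1 and Col1a2. Ameloblast markers made up 2.23% to 9.21% there. In the stratum intermedium libraries odontoblast and pulp markers made up 1.76% to 4.71%, against 0.621% to 1.24% for that layer's own list. Both captures therefore held transcripts of tissue other than the named cells.

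**Figure D2:**
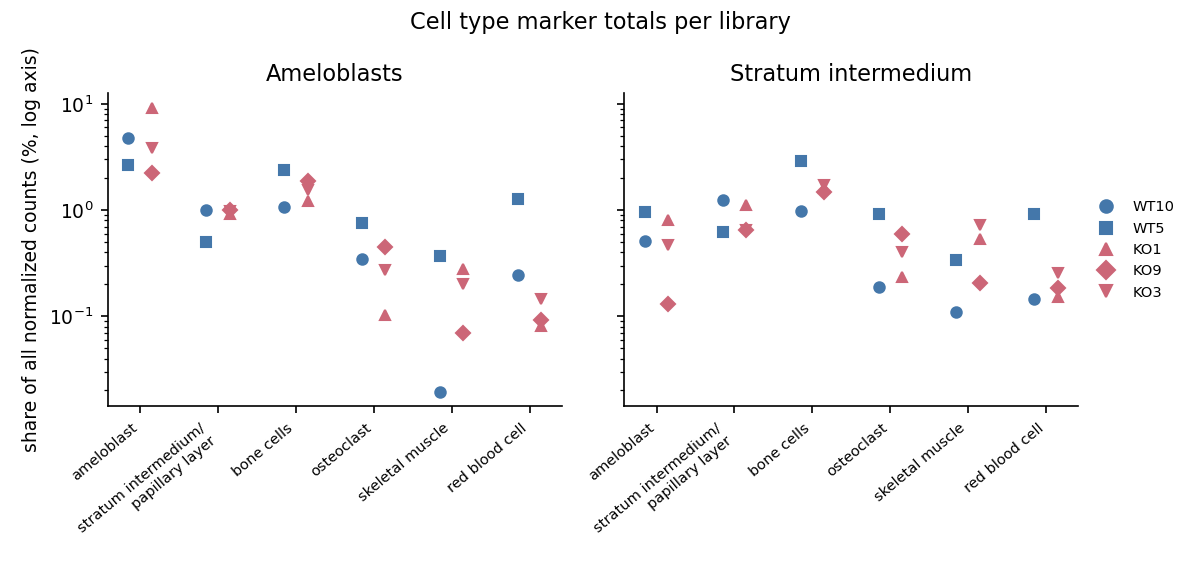
Share of all normalized counts, in percent on a log axis, taken by the marker genes of 6 cell types; each point is 1 library, in blue for WT and red for KO, with symbols for the library prefixes. Red blood cell markers took 0.244% and 1.28% of the WT ameloblast libraries and at most 0.144% of the KO ameloblast libraries.

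The comparison of KO with WT ameloblast captures asked which transcripts differ without claudin-10. The captures were not pure, so a difference may come from other cells in them. The 10 named genes with the smallest p-values were all higher in KO, each with its 3 KO libraries above both WT libraries. Enpp2 (ENSMUSG00000022425), which encodes autotaxin, the enzyme that makes lysophosphatidic acid, averaged 2379 ± 349 in WT (SD, n = 2) and 10398 ± 2533 in KO (SD, n = 3), with a log2 difference of 2.11 (SE 0.27). Slc39a8 (ENSMUSG00000053897), a zinc and manganese importer, averaged 958.1 and 3809 (log2 1.93, SE 0.31). Several encode membrane or junction proteins. The desmosomal cadherin Dsc3 (ENSMUSG00000059898) averaged 1073 and 3392 (1.62, SE 0.30), the cadherin Cdh6 (ENSMUSG00000039385) 353.3 and 1388 (1.93, SE 0.35), the claudin Cldn6 (ENSMUSG00000023906) 108.6 and 473.8 (2.07, SE 0.43) and the actin-binding junction gene Pof1b (ENSMUSG00000034607) 34.4 and 206.3 (2.53, SE 0.53). Among transporters, Cnnm4 (ENSMUSG00000037408), which encodes a magnesium transporter required for enamel mineralization, averaged 1489 and 3639 (1.28, SE 0.23), and Slc4a4 (ENSMUSG00000060961), a sodium bicarbonate cotransporter, averaged 279.4 and 828.4 (1.63, SE 0.35). The membrane glycoprotein gene Gpm6b (ENSMUSG00000031342) averaged 795.2 and 2102 (1.41, SE 0.23), and the ephrin receptor gene Epha7 (ENSMUSG00000028289) averaged 227.1 and 591.3 (1.38, SE 0.29).

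None of these differences passed correction over all genes. Of 16212 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.989. An unadjusted p under 0.05 was found for 498 genes, of which 365 were higher and 133 lower in KO. Without KO replicate 1, 2 or 3 that count was 245, 474 or 265. It was larger when either WT library was left out, which leaves 1. With sex as a covariate, where the KO difference is that of KO9 alone, more of such genes were lower than higher. The KO and WT libraries did not overlap for 18.4% of genes, where chance gives 20%. In the limma fit without WT replicate 2, in which the lone WT library is assumed to vary like the KO libraries, 1 gene passed, the muscle gene Tcap (adjusted p = 0.0496), which was listed at 0 in WT replicate 1 and was named after its value was seen. On simulated data with the same design over 16212 genes, limma recovered 28% of genes changed by 2 on the log2 scale and 62% of those changed by 4.

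**Figure D3:**
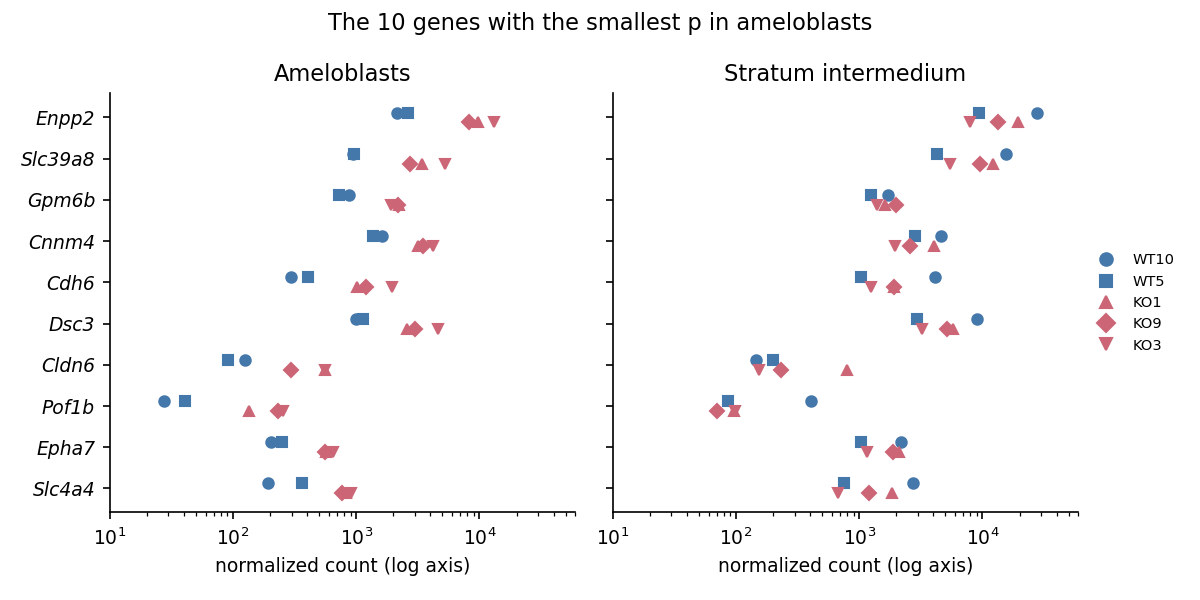
Normalized counts, on log axes, of the 10 genes with the smallest p-values in ameloblasts, in both cell types; each point is 1 library, in blue for WT and red for KO, with symbols for the library prefixes. In ameloblasts, the KO libraries of Enpp2 lay between 8199 and 13167 and the WT libraries at 2132 and 2626.

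Groups of related genes were also tested. Of 41 lists tested with camera at a preset correlation of 0.01, 14 passed an adjusted p of 0.05 in ameloblasts, 8 of them higher and 6 lower in KO. Of the 10 splits of the 5 libraries into 2 and 3, 3 gave at least as many lists, counting the real one. With an estimated correlation 0 passed (smallest adjusted p = 0.39, 2 lists at an unadjusted p under 0.05), and with fry 0 passed (3 lists). Each of the 10 splits gave 0 lists with an estimated correlation, so that count cannot set the real split apart. Estimated correlations were 0.63 for ribosomal protein genes and 0.929 for red blood cell markers. The sodium, potassium, chloride and magnesium transport list had one of -0.000577, under the preset 0.01. Its unadjusted camera p still went from 0.0103 to 0.0666, so a lost call need not reflect correlated genes. In a fit with sex as a covariate, added after the data were seen, the KO difference is that of KO9 alone, the only KO prefix of the same sex as both WT prefixes. In that fit, which cannot separate sex from the choice of a single KO library, 9 lists passed in camera, and 4 of the 14 were among them: adherens and gap junction genes, Notch pathway genes, ribosomal protein genes and red blood cell markers. Within single lists, 9 memberships in 6 lists passed when adjusted over the list alone, against 0 over all genes tested. Only the Notch pathway, cytosolic ribosomal protein and red blood cell lists, 3 of the 14, kept their calls when each of the 5 libraries was left out in turn.

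Cell junction genes were higher as groups in KO ameloblasts. Of 13 claudins other than Cldn10, 10 were higher in KO, with a median log2 difference of 0.95 (adjusted p = 0.00322 in camera; adjusted p = 0.429 with an estimated correlation). Cldn6 passed when adjusted over the list alone (adjusted p = 0.0244). Cldn1 averaged 525 ± 397 in WT and 1509 ± 642 in KO, Cldn8 180.7 ± 122 and 425.6 ± 30.6, and Cldn4 141.5 ± 91.1 and 358.7 ± 147. Without WT replicate 1 the claudin list had an adjusted p of 0.176, and with sex as a covariate the claudin and desmosome lists had adjusted p-values of 0.305 and 0.325. Of 21 desmosome and hemidesmosome genes, 19 were higher (median log2 0.34, adjusted p = 0.00287; adjusted p = 0.39 with an estimated correlation), and Dsc3 passed when adjusted over the list alone (adjusted p = 0.0215). The desmosomal cadherin Dsg1a averaged 768.7 ± 248 and 1682 ± 495. Of 18 adherens and gap junction genes, 13 were higher (median log2 0.49, adjusted p = 0.0193; adjusted p = 0.39 with an estimated correlation). The connexin gene Gja1 averaged 56024 ± 27743 in WT and 100604 ± 8219 in KO, and Nectin4 381.3 ± 189 and 1364 ± 548. The desmosome list without WT replicate 2 had a camera adjusted p of 0.558 and the adherens and gap junction list one of 0.492, and without KO replicate 2 the latter had one of 0.102. Other tight junction genes did not pass as a list (17 of 30 higher, adjusted p = 0.275), although occludin (Ocln) averaged 150.3 ± 105 and 507.9 ± 182 and F11r averaged 2079 ± 676 and 3784 ± 461.

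The markers of the stratum intermedium and the papillary layer, its successor at the maturation stage, were also higher in KO ameloblasts, in 12 of 14 genes (median log2 0.49, adjusted p = 0.00263; adjusted p = 0.39 with an estimated correlation). This list shares 11 of its 15 genes with other lists. Dsc3 passed when adjusted over the list alone (adjusted p = 0.0143), and the keratin Krt17 averaged 6399 ± 2294 in WT and 17665 ± 8066 in KO. As a share of all counts, these markers took 1.01% and 0.499% of the WT libraries and 0.915% to 1.0% of the KO libraries (exact permutation p = 0.4). Notch pathway genes, active in the stratum intermedium, were higher in 14 of 16 cases (median log2 0.45, adjusted p = 0.00267; adjusted p = 0.39 with an estimated correlation). The Notch ligand Jag1 averaged 1920 ± 429 and 2783 ± 354, and the target gene Heyl averaged 409.5 ± 72.2 and 745.2 ± 91.2. Sodium, potassium, chloride and magnesium transport genes were higher in 17 of 22 cases (median log2 0.23, adjusted p = 0.0325; adjusted p = 0.39 with an estimated correlation). In that list Cnnm4 passed when adjusted over the list alone (adjusted p = 0.0196). The marker list had an adjusted p of 0.0932 without WT replicate 2, and the transport list had one of 0.327 without WT replicate 1 and 0.114 without KO replicate 3. Their adjusted p-values were 0.0551 and 0.466 with sex as a covariate.

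Genes of enamel formation itself did not pass as lists in ameloblasts. Of 18 secretory-stage enamel genes, 15 were higher in KO (median log2 0.36, adjusted p = 0.0986 in camera). The enamel protease Mmp20 averaged 17164 ± 9067 in WT and 24462 ± 12498 in KO, and ameloblastin (Ambn) averaged 87615 ± 33684 and 148628 ± 132736. Amelogenin (Amelx) took 2.04% and 3.75% of the WT libraries and 1.75% to 6.35% of the KO libraries. The 16 measured maturation-stage genes were split evenly, with a median log2 difference of -0.02 (adjusted p = 0.707), and of these Slc4a4 passed when adjusted over the list alone (adjusted p = 0.035). Unfolded protein response genes were higher in 19 of 25 cases (median log2 0.32, adjusted p = 0.0339; adjusted p = 0.79 with an estimated correlation). The protein disulfide isomerase Pdia6 averaged 15532 ± 354 and 27310 ± 10469. This list had an adjusted p of 0.558 without WT replicate 2 and of 0.588 without KO replicate 1, and with sex as a covariate it turned direction (adjusted p = 0.552). With library weights it had an adjusted p of 0.0522.

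Cytosolic ribosomal protein genes were lower in KO ameloblasts in 28 of 28 cases (median log2 -0.34, adjusted p = 1.9e-10; adjusted p = 0.622 with an estimated correlation). Rpl28 averaged 5970 ± 492 in WT and 4050 ± 203 in KO. Mitochondrially encoded genes were lower in 10 of 13 cases (median log2 -0.25, adjusted p = 0.0193; adjusted p = 0.79 with an estimated correlation). Immediate early and heat shock genes were lower in 15 of 23 cases (median log2 -0.25, adjusted p = 0.0105; adjusted p = 0.39 with an estimated correlation), among them Ier3 at 1188 ± 64.7 and 585.7 ± 270. Interferon response genes were lower in 14 of 20 cases (median log2 -0.31, adjusted p = 0.0193; adjusted p = 0.79 with an estimated correlation), among them the RNA sensor Ifih1 at 242.2 ± 26.6 and 60.0 ± 31.7. On leaving out WT replicate 2, the mitochondrial list had an adjusted p of 0.611, the immediate early list one of 0.0981, and the interferon list one of 0.558 with the opposite direction. The mitochondrial call was also lost without KO replicate 1 (adjusted p = 0.167) and under quantile normalization (adjusted p = 0.0658), and the immediate early call without WT replicate 1 (adjusted p = 0.0682) or KO replicate 3 (adjusted p = 0.114). With sex as a covariate the mitochondrial, immediate early and interferon lists had adjusted p-values of 0.316, 0.651 and 0.0866 in camera. With library weights the mitochondrial and interferon lists had adjusted p-values of 0.139 and 0.216.

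As lists, markers of blood and bone-resorbing cells were lower in KO ameloblast libraries, and muscle markers were higher. All 5 measured red blood cell markers were lower (median log2 -2.33, adjusted p = 3.57e-08; adjusted p = 0.39 with an estimated correlation), and the 4 globin genes passed when adjusted over the list alone. Hba-a2 averaged 67538 ± 59925 in WT and 10597 ± 2397 in KO. All 7 osteoclast markers were lower (median log2 -1.06, adjusted p = 0.000647; adjusted p = 0.622 with an estimated correlation), among them Mmp9 at 27267 ± 11773 and 10969 ± 6212. All 11 skeletal muscle markers were higher (median log2 1.09, adjusted p = 0.0105; adjusted p = 0.79 with an estimated correlation), among them myoglobin (Mb) at 15.4 ± 21.8 and 74.5 ± 52.8. As a share of all counts, muscle markers were not higher in KO, with means of 0.194% in WT and 0.184% in KO (exact permutation p = 1), and WT replicate 2 held the highest share, 0.368%. The osteoclast list had an adjusted p of 0.441 without WT replicate 2. The muscle list had an adjusted p of 0.113 with the opposite direction without WT replicate 1, and one of 0.17 without KO replicate 1. The osteoclast list had an adjusted p of 0.74 with sex as a covariate, and in that fit the muscle list turned direction (adjusted p = 0.914).

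**Figure D4:**
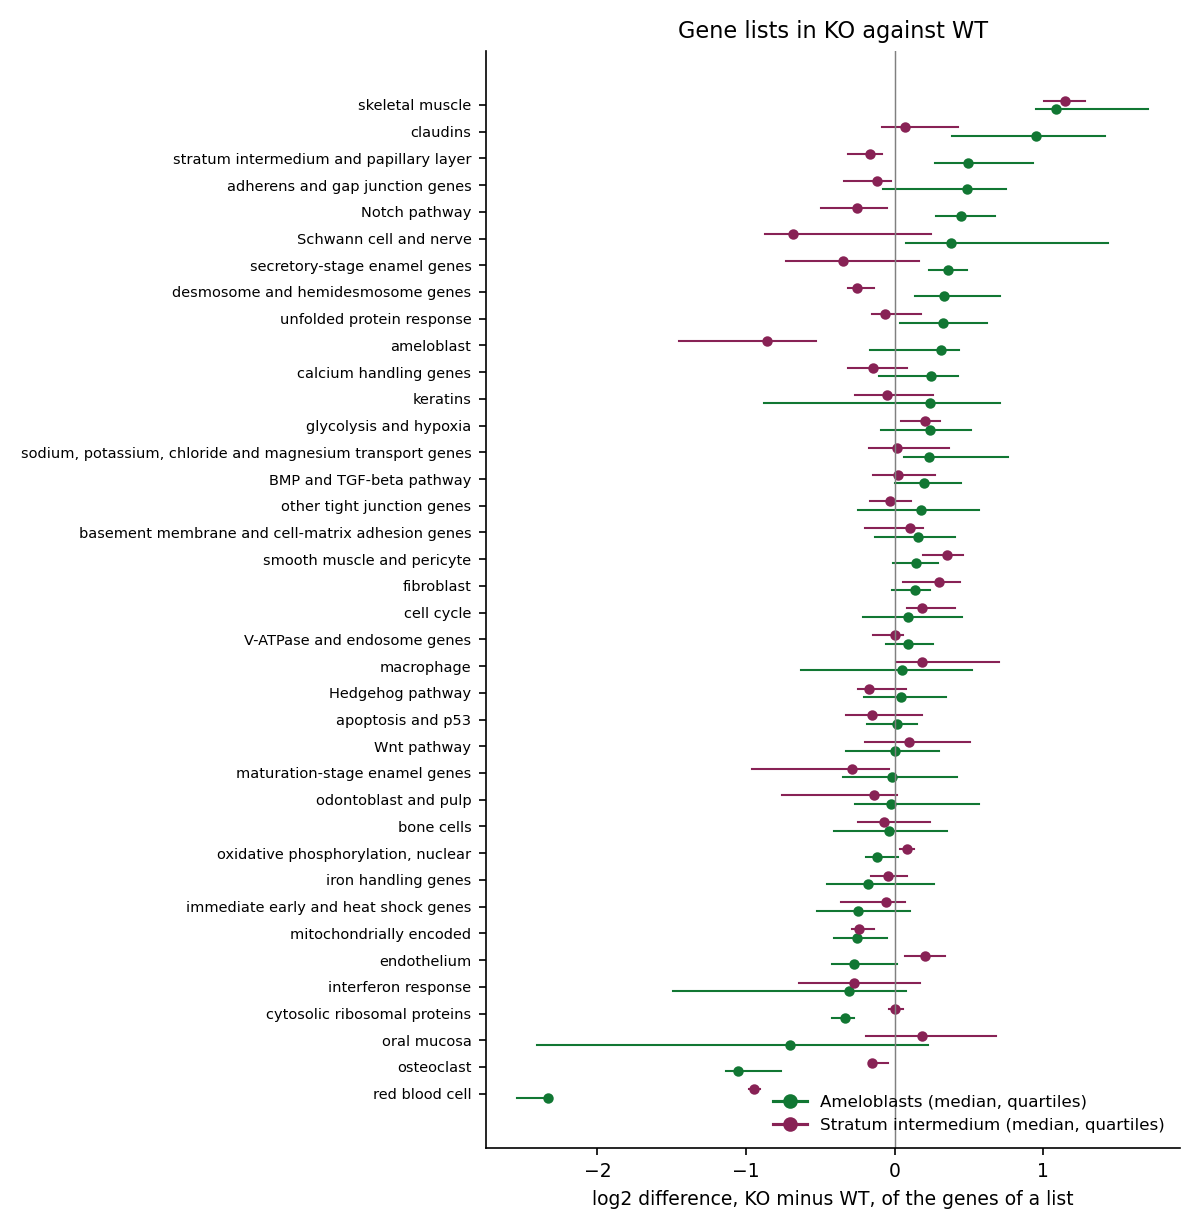
Median log2 difference, KO minus WT, over the measured genes of a list, with lines from the lower to the upper quartile, for ameloblasts (green) and the stratum intermedium (purple). The neutrophil, lymphocyte and adipocyte lists, with few measured genes, are not drawn. Cytosolic ribosomal protein genes had a median of -0.34 in ameloblasts and 0.00 in the stratum intermedium.

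In the stratum intermedium, the comparison asked the same question of the supporting layer. Besides Cldn10, the gene with the smallest p-value was Zfp865, a zinc finger gene (ENSMUSG00000074405, chromosome 7, 5020376 to 5036768), which averaged 1088 ± 28.4 in WT (SD, n = 2) and 43.4 ± 17.2 in KO (SD, n = 3), with a log2 difference of -4.69 (SE 0.50; adjusted p = 0.404 in limma). Setdb2 (ENSMUSG00000071350), which encodes a histone methyltransferase of the SET domain family, averaged 346.3 and 92.3 (log2 -1.91, SE 0.43), the transporter gene Abca8a (ENSMUSG00000041828) 379.2 and 104.6 (-1.85, SE 0.46), and Hmgcs1 (ENSMUSG00000093930), an enzyme of cholesterol synthesis, 3008 and 1746 (-0.79, SE 0.20). Higher in KO were Gpld1 (ENSMUSG00000021340), a phospholipase that cleaves GPI anchors, at 7.64 and 110.2 (13.9-fold on the log2(value + 1) scale), the neuronal calcium-binding gene Caln1 (ENSMUSG00000060371) at 0.786 and 60.1 (5.19, SE 1.22), the fast skeletal myosin Myh1 (ENSMUSG00000056328) at 52.6 and 548.6 (3.69, SE 0.91), the complement protease gene Masp1 (ENSMUSG00000022887) at 260.9 and 637.8 (1.30, SE 0.32) and the mitotic spindle gene Fam83d (ENSMUSG00000027654) at 405.7 and 837.8 (1.04, SE 0.26). For all of these the WT and KO libraries did not overlap. Caln1 stood under 10 in both WT libraries, so the KO libraries alone brought it past the floor. Myh1 belongs to the skeletal muscle list, whose markers took 0.11% and 0.341% of the WT libraries and 0.207% to 0.728% of the KO libraries (exact permutation p = 0.3).

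Of 16543 genes tested with limma in the stratum intermedium, 0 had an adjusted p under 0.05. An unadjusted p under 0.05 was found for 340, of which 210 were higher and 130 lower in KO. Without KO replicate 1, 2 or 3 that count was 256, 264 or 236, of which 114, 143 and 112 were higher. The count was larger when either WT library was left out, with opposite balances. With sex as a covariate, where the KO difference is that of KO9 alone, more of such genes were lower than higher. The WT and KO libraries did not overlap for 15.2% of genes, where chance gives 20%. Simulated changes of 2 and 4 on the log2 scale were recovered in 32% and 60% of genes among the 16543.

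Of the 41 lists, 8 passed in camera in the stratum intermedium, 3 higher and 5 lower in KO. Of the 10 splits of these libraries into 2 and 3, 8 gave at least as many lists, counting the real one. With an estimated correlation 0 passed (smallest adjusted p = 0.809, 1 list at an unadjusted p under 0.05), and with fry 0 passed (2 lists). Here too each of the 10 splits gave 0 lists with an estimated correlation, so that count cannot set the real split apart. Skeletal muscle markers were higher in 10 of 11 cases (median log2 1.15, adjusted p = 0.000134; adjusted p = 0.809 with an estimated correlation), and Myh1 passed when adjusted over the list alone (adjusted p = 0.0498). Smooth muscle and pericyte markers were higher in 8 of 9 cases (median log2 0.35, adjusted p = 0.0211; adjusted p = 0.809 with an estimated correlation), among them Myh11 at 76.7 ± 23.0 in WT and 201.0 ± 50.7 in KO. Cell cycle genes were higher in 20 of 23 cases (median log2 0.18, adjusted p = 0.0414; adjusted p = 0.906 with an estimated correlation), among them the spindle checkpoint kinase Bub1b at 254.5 ± 14.4 and 536.9 ± 78.9. Mitochondrially encoded genes were lower in 11 of 13 cases (median log2 -0.24, adjusted p = 0.00141; adjusted p = 0.809 with an estimated correlation), among them mt-Atp6 at 46991 ± 7392 and 33942 ± 3046. The mitochondrial and skeletal muscle lists kept their calls when each library was left out in turn, and lost them with sex as a covariate (adjusted p = 0.162 and 0.59). The smooth muscle and red blood cell lists lost theirs in the same fit (adjusted p = 0.0781 and 0.0726), which rests on KO9 as the only KO library, and the mitochondrial list also lost its call with library group as a block (adjusted p = 0.0751).

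Ameloblast markers were lower in the KO stratum intermedium in 9 of 11 cases (median log2 -0.86, adjusted p = 0.0229; adjusted p = 0.809 with an estimated correlation). Amelx averaged 120511 ± 64626 in WT and 69461 ± 50539 in KO, and the ameloblast transcription factor Sp6 averaged 2980 ± 1362 and 1832 ± 439. With a filter of a mean of at least 50 this list had an adjusted p of 0.0515. All 12 markers of this list also stand in the enamel lists. Ameloblast markers took 0.509% and 0.954% of the WT libraries and 0.131% to 0.8% of the KO libraries (exact permutation p = 0.4). Notch pathway genes were lower in 12 of 16 cases (median log2 -0.26, adjusted p = 0.0414; adjusted p = 0.809 with an estimated correlation), with Jag1 at 2230 ± 512 and 1454 ± 289. Desmosome and hemidesmosome genes were lower in 18 of 21 cases (median log2 -0.25, adjusted p = 0.0414; adjusted p = 0.906 with an estimated correlation), with the desmosomal cadherin Dsg3 at 437.9 ± 194 and 251.1 ± 42.4. Red blood cell markers were lower in 5 of 6 cases (median log2 -0.95, adjusted p = 0.0414; adjusted p = 0.906 with an estimated correlation), and took 0.146% and 0.911% of the WT libraries and 0.152% to 0.258% of the KO libraries.

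Most of these stratum intermedium calls depended on single libraries. Without WT replicate 1 the desmosome list was higher in KO, with an adjusted p of 0.0146, the Notch list had an adjusted p of 0.665 and the ameloblast list one of 0.0952. Without WT replicate 2 the direction of the cell cycle list (adjusted p = 0.585) and of the red blood cell list (adjusted p = 0.14) turned, and the smooth muscle list (adjusted p = 0.272) and the ameloblast list (adjusted p = 0.0966) lost their calls. Without KO replicate 3 the cell cycle list turned again (adjusted p = 0.916), and the Notch, desmosome, ameloblast and red blood cell lists had adjusted p-values of 0.338, 0.543, 0.52 and 0.172. Without KO replicate 1 the Notch, desmosome, cell cycle and smooth muscle lists had adjusted p-values of 0.21, 0.221, 0.0791 and 0.0791, and without KO replicate 2 the red blood cell list had one of 0.0669. The number of lists passing ranged from 4 to 21 over these fits, against 8 with all libraries.

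The last comparison asked whether the KO difference was the same in both cell types, using the ameloblast minus stratum intermedium difference within each library prefix. Zfp865 had the smallest p-value, with log2 differences of -0.41 in ameloblasts and -4.69 in the stratum intermedium (difference 4.28, SE 0.28, adjusted p = 0.263 in limma). Next by p-value came the kinase gene Pim2 (0.70 and -2.00), Setdb2 (0.54 and -1.91), the lipid barrier gene Nipal4 (1.01 and -1.36) and the adaptor gene Nck2 (0.54 and -1.67). Each had an adjusted p of 0.864. This order is not one of size, as Pof1b stood further apart than these, at 2.53 and -1.11. Of 15567 genes, 0 passed in limma and 747 had an unadjusted p under 0.05. That count was 672 without KO1, 694 without KO9 and 583 without KO3. It was larger without WT5 and smaller without WT10, each of which leaves 1 WT prefix. In the simulation, 0% of changes of any size up to 8 on the log2 scale were recovered over the 15567 genes. The simulation took each gene's estimated spread as its true one, so this share may not be that of the data. Of the 41 lists, 6 passed in camera, 3 relatively higher and 3 relatively lower in ameloblasts, and 0 passed with an estimated correlation (adjusted p = 0.824 for each of the 6; 1 list at an unadjusted p under 0.05) or with fry. Desmosome and hemidesmosome genes (median log2 0.34 and -0.25), Notch pathway genes (0.45 and -0.26) and stratum intermedium markers (0.49 and -0.17) were relatively higher in KO ameloblasts, with adjusted p-values of 0.0107, 0.00931 and 0.00806. Cytosolic ribosomal protein genes (-0.34 and 0.00), red blood cell markers (-2.33 and -0.95) and osteoclast markers (-1.06 and -0.15) were relatively lower, with adjusted p-values of 1.5e-05, 1.5e-05 and 0.00806. Without prefix WT10 the desmosome, Notch, marker and osteoclast lists had adjusted p-values of 0.361, 0.239, 0.434 and 0.456. Without KO9 the first 3 of these had 0.0793, 0.0894 and 0.0793, and without KO3 the desmosome and marker lists had 0.0967 and 0.0518. The number of passing lists ranged from 3 without KO9 to 14 without WT10, where only 2 of the 6 were among the 14.

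The genes ranked highest in ameloblasts were also measured in the stratum intermedium. All 10 had higher values in the WT stratum intermedium than in WT ameloblasts, from 1.6-fold for Cldn6 to 10.3-fold for Slc39a8. The tables had been normalized separately. These genes were picked for being higher in KO than in the same 2 WT ameloblast libraries, which by itself favours such ratios. Among all genes, 1510 were at least 4-fold higher in the stratum intermedium library of WT10 and 912 in its ameloblast library. In WT5 these numbers were 140 and 69. Enpp2, for example, stood at 2379 in WT ameloblasts, 10398 in KO ameloblasts and 18537 in the WT stratum intermedium. Gpm6b and Cldn6 had a mean in KO ameloblasts above the higher WT stratum intermedium library, and 8 of the 10 genes had one above the lower WT stratum intermedium library.

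Few differences were shared by the cell types. In both, 9 genes had an unadjusted p under 0.05 with no overlap between WT and KO libraries, where each of these was named after its values were seen. Cldn10 and Abca8a were lower in both. Fam83d, Mmp23, Tspan15, Lgalsl, Uevld, Arxes2 and Gabrr2 were higher in both, and their adjusted p-values over all genes were 0.989 in ameloblasts and 1 in the stratum intermedium in limma. Gabrr2, a GABA receptor subunit gene, was listed at 0 in all 4 WT libraries, at 17.4 to 26.9 in KO ameloblasts and at 14.7 to 26.2 in the KO stratum intermedium. It was listed through the 3 KO libraries alone. A gene found in the 2 WT libraries alone could not be listed, so such a difference could appear in 1 direction only. Among genes with an unadjusted p under 0.05, 8 were higher in both cell types, where 4.26 are expected of independent lists. Lower in both were 4, Cldn10 itself among them, where 1.08 are expected. The same prefixes supply both cell types, so independence is not the value to expect without a KO effect. The excess is therefore no sign of a shared KO effect. Across 15567 genes, which are not independent replicates, the KO differences of the cell types were correlated at Pearson's r = 0.073 and Spearman's rho = 0.042. The other 9 splits of the prefixes into 2 and 3 gave r from 0.102 to 0.37, and r without WT10 was 0.268.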

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

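The tests of stratum intermedium cells in the ameloblast captures were chosen only after the result was seen. In 6 gene lists the KO difference was not the same in both cell types, by camera on the difference within each prefix. Adjusted p-values were 1.5e-05 for cytosolic ribosomal protein genes, 1.5e-05 for red blood cell markers, 0.00806 for osteoclast markers, 0.00806 for stratum intermedium and papillary layer markers, 0.00931 for Notch pathway genes and 0.0107 for desmosome and hemidesmosome genes. With an estimated correlation each had an adjusted p of 0.824. The ribosomal and red blood cell lists passed without each prefix in turn, with adjusted p-values of up to 0.048 and 0.00463, and the others lost their calls without prefix WT10.

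The 10 genes with the smallest p-values in KO ameloblasts were all higher in the WT stratum intermedium than in WT ameloblasts, and stratum intermedium markers were higher as a list. The 10 genes were picked through the same WT ameloblast libraries, which favours that ratio, so it is no independent sign of admixture. More stratum intermedium cells in the KO ameloblast captures would raise the genes of that layer together. Over 1510 genes at least 4-fold higher in the stratum intermedium than in the ameloblast library of prefix WT10, the median log2 difference between KO ameloblasts and the ameloblast library of WT5 was -0.562, and it was -0.475 for the 828 of them that were at or above 10. Picked in WT5, 140 genes had a median of 0.498 against WT10. Genes at least 4-fold higher in the ameloblast library of the picking prefix were the comparison. Their medians were -0.109 against WT5 (912 genes picked in WT10) and 0.279 against WT10 (69 genes picked in WT5). The sign therefore followed the WT reference for both kinds of genes. The outcome thus turned on the roles of the WT libraries, as the gene set and the reference changed together, and admixture stays open. In the ameloblast library that picked them, 390 of the 1510 genes and 8 of the 140 were listed at 0. The KO ameloblast mean lay above the higher WT stratum intermedium library for 2 of the 10 genes, Gpm6b and Cldn6, and above the lower one for 8, so this count turned on the library too.

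The sex of the mice may also contribute, since KO1 and KO3 carried Xist and both WT prefixes did not. In KO9, the KO prefix without Xist, the 1510 and the 140 genes had medians of -0.559 and 0.843. These were -0.56 and 0.523 in KO1 and -0.247 and 0.737 in KO3, so KO9 did not stand apart from both. The only KO library of that kind does not separate sex from genotype. A change of the ameloblasts themselves stays open as an untested hypothesis.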

How the results depend on the processing

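The fits with sex as a covariate, and the list tests under pseudocounts, filters, rescaling and library weights, were chosen only after the result was seen. Of the alternative values of the main results, 124 stayed within the limits set for them, 2 were weaker and 17 counts or correlations moved. Of those of single lists, 332 kept their call, 111 lost it and 9 turned direction. Robust variance cannot change the call of a list, and the looser threshold cannot take a call from a list that passed. Both were left out of these counts of single lists. The looser threshold can add calls. With it 15 lists passed in ameloblasts and 12 in the stratum intermedium, against 14 and 8 at the main threshold. For the difference 6 passed at either threshold. The looser threshold was applied to lists only after the result was seen. With replicate number, library group or sex in the fit, some KO libraries drop out of the KO difference, as described below. Why the values moved under the other alternatives is not known, as the cause was not tested. Tests on whole reads with edgeR and DESeq2 were planned and not run, because whole reads could not be recovered.

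With library weights, Cldn10 in ameloblasts had a log2 difference of -0.97. On leaving out each library in turn it ranged from -1.71 to -0.99 and lost its call without WT replicate 2 (-1.22), and in the stratum intermedium from -3.68 to -2.06. The number of genes past the threshold in ameloblasts ranged from 0 to 1, and it was 0 in every such fit of the stratum intermedium and of the difference. Where 1 WT library was left, it was assumed to vary like the other group.

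Where 14 lists passed in ameloblasts, 9 did so with sex as a covariate, of which 4 were among the 14, and 11 of the 14 kept their calls with library weights. With an estimated correlation 0 passed and with fry 0, and without single libraries from 12 to 21. In the stratum intermedium the number fell from 8 to 0 with an estimated correlation and to 0 with fry, and ranged from 4 without KO replicate 1 to 21 without WT replicate 1. For the difference it fell from 6 to 0 with an estimated correlation and to 0 with fry, and ranged from 3 without KO9 to 14 without WT10. These ranges count lists past the threshold, not the same lists. In each cell type all 10 splits gave 0 lists with an estimated correlation. With sex as a covariate 4 of the 8 stratum intermedium lists and 4 of the 6 lists of the difference kept their calls. The correlation of the KO differences ranged from 0.032 without KO1 to 0.268 without WT10.

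With sex as a covariate the KO difference is that of KO9 alone against both WT prefixes, with the lone library assumed to vary like the others. In that fit the unfolded protein response list (adjusted p = 0.552) and the skeletal muscle list (0.914) of ameloblasts turned direction. Without single libraries, the adjusted p of the ameloblast muscle list ranged from 4.52e-09 to 0.17 and turned at 0.113, and that of the interferon list ranged from 5.11e-05 to 0.558 and turned at the latter. In the stratum intermedium, the desmosome list ranged from 9.53e-07 to 0.543 and turned at 0.0146, the cell cycle list ranged from 4.12e-06 to 0.916 and turned at 0.585 and 0.916, and the red blood cell list ranged from 2.82e-12 to 0.172 and turned at 0.14.

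With the replicate number as a replicate block, KO replicate 3 has no WT partner and drops out of the KO difference, and Cldn10 stood at -1.71 in ameloblasts and -2.73 in the stratum intermedium, as it did without that library. In that fit 4 lists passed in the stratum intermedium, 3 of them among the 8, where the cell cycle list turned (adjusted p = 0.737) and the desmosome (0.5), Notch (0.317), ameloblast (0.317) and red blood cell (0.0991) lists lost their calls. In ameloblasts 15 passed, 11 of them among the 14, and the transport (0.0931), immediate early (0.113) and skeletal muscle (0.0587) lists lost their calls. With library group as a replicate block, in which KO1 drops out likewise, these numbers were 18 and 16, and calls were lost by the unfolded protein response (0.696) and mitochondrial (0.148) lists of ameloblasts and the mitochondrial list of the stratum intermedium (0.0751). The replicate numbers do not follow the prefixes, as KO replicate 1 is KO1 in ameloblasts and KO3 in the stratum intermedium. After the mean of each genotype was taken off each gene, WT and KO libraries with the same number were correlated at 0.0862 and -0.116 in ameloblasts. In the stratum intermedium they were correlated at -0.186 and -0.133. Those with the same library group were correlated, centred in the same way, at 0.116 and 0.273 in ameloblasts and at 0.00593 and 0.186 in the stratum intermedium. All values by library group were positive, but 1 was under the 0.1 required of every pair, so that block stayed an alternative. With 2 WT libraries the centred WT values mirror each other, so a KO library's correlations with them differ only in sign. These correlations are therefore not separate checks and cannot decide a pairing.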

Other observations

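The test of an inherited variant at Zfp865, the comparison with runs of neighbouring genes and the mean of both cell types were chosen only after the result was seen. The 10 splits of 5 libraries cannot give a share under 0.05, so they could not have set the count of passing lists apart from chance. In ameloblasts the real split gave 14 lists and the highest other split 15, with 3 of 10 splits giving as many as the real one. In the stratum intermedium these numbers were 8 and 17, with 8 of 10. Neither count stood out, as other splits gave as many or more. The real split gave 498 genes at an unadjusted p under 0.05 in limma in ameloblasts and 340 in the stratum intermedium. Setting WT10 and KO1 apart gave the most of the 10 splits, 1557 and 2068, and was picked after the values were seen. Setting KO1 and KO3, the prefixes with Xist, apart gave 696 and 446, and KO9 and KO3 gave 193 and 335. Groupings other than genotype could thus give more such genes, and what lies behind them was not tested.

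Zfp865 was lower in the KO stratum intermedium (log2 difference -4.69) and stood at -0.41 in ameloblasts. The 95% interval of the ameloblast difference reached from -1.46 to 0.63, and so left out the stratum intermedium value. Zfp865 had the smallest p of both the stratum intermedium test and the difference test. The interval therefore restates how the gene was picked, and cannot decide on an inherited variant that lowers it alike in both cell types. WT ameloblast libraries stood at 170.2 and 208.3, and WT stratum intermedium libraries at 1068 and 1108, in separately normalized tables. Among measured genes that overlap Zfp865, the smallest unadjusted p was 0.0694 in limma (Zfp784), which does not exclude a change. KO minus WT means were 118 normalized counts for Ccdc106, -129 for Zfp784 and -0.05 for Gm44973, against -1044 for Zfp865. Reads counted for a measured neighbour instead would therefore not cover the fall. The overlapping gene 4632433K11Rik was not measured, so shared reads stay open. An effect limited to the stratum intermedium may remain as a hypothesis, and its adjusted p over all genes was 0.404.

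Dct, a melanin synthesis gene that ends at 118052244 on chromosome 14, ahead of the start of Cldn10 at 118787908, was higher in KO in both cell types, with log2 differences of 2.31 (SE 0.78) in ameloblasts and 1.55 (SE 0.65) in the stratum intermedium, although WT and KO libraries overlapped in the latter, where WT replicate 1 stood at 504.5 and KO replicate 1 at 437.6. A chromosome segment from the strain in which Cldn10 was targeted, kept by linkage, may explain differences near the gene. Of 27 other genes within 5 Mb, 3 (11.1%) had an unadjusted p under 0.05 for the mean of both cell types, against 222 of 15538 elsewhere (1.43%, Fisher's exact p = 0.00675). These were Gpc6 (-1.15) and Gpr180 (-0.59), lower in KO, and Gpc5 (1.65), higher. Neighbouring genes are not independent, and 109 of 15013 runs of 27 neighbouring genes (0.726%) held as many. A regulatory effect of the lost Cldn10 sequence on its neighbours was not tested.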
